A study of Homo sapiens with 12 samples.

How the data were processed

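RNA from 12 pancreatic fibroblast cultures, 9 of cancer associated fibroblasts (CAF) and 3 controls, was measured on Affymetrix Human Exon 1.0 ST arrays, which carry short probe sets along the exons of each gene. One array was run per culture. Per the labels, total RNA was extracted with a column kit and biotin-labelled cDNA was made from amplified cRNA. Per the submitters' processing notes and the labels, the authors made the values with RMA in Affymetrix Expression Console, as a core exon analysis. RMA subtracts background, sets all arrays to one distribution and summarises the probes of each probeset, so the deposited unit is a log2 signal per exon probeset, relative and without an absolute scale. Because RMA makes the array distributions equal, a change of most genes in one direction would be removed from these values. The software version, the probeset annotation release and the genome build are not given in the sources used here, and no coordinates are printed for that reason. Per the series' design text the authors compared the groups in Partek, with a test not given in the sources used here.

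The deposited table held 232448 probesets in 12 arrays, and 0 per-sample columns were left unused. Genes were assigned from the platform's probe annotation, where 216780 probesets had 1 gene symbol, 2335 had several and 13333 had none. Probesets with several symbols named no gene. Of 16573 symbols, 14260 were current in the RefSeq gene table of assembly GRCh38.p14, used for names only, 2227 were updated through a unique synonym and 86 were kept as given. XIST, TSIX and Y-linked genes, 24 genes with 195 probesets, were left out of every step. The median of each array's log2 values lay between 4.81 and 4.87, and the upper and lower quartiles between 6.98 and 7.12 and between 2.93 and 3.11. The number of arrays and their unequal spread both limit the precision here. The interquartile range of relative log expression, the difference of each probeset from its median over arrays, was widest in CAF 8 at 0.726 and control 1 at 0.689, and 0.408 at the narrowest. No pair of arrays held the same values.

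A gene's value was the mean of the log2 values of its probesets, for the 15377 genes with at least 3 probesets (median 11 probesets per gene over all 16519 genes). Genes above the 30th percentile of an array in at least 3 arrays were tested, 11489 in all. CAF and control were compared with limma (version 3.58.1, lmFit and eBayes, 2-sided, R 4.3.3), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The same fit was run on 178161 single probesets. Differential exon usage was tested with limma's diffSplice F test in 13467 genes, and it asks whether the probesets of a gene differ between groups by unequal amounts. In each fit the 12 arrays formed 2 groups with no covariate. The labels do not name the groups, which were inferred from the disease status of each culture and the numbers in the series' design text. Fold changes are 2 to the power of the difference of mean log2 values. The p-values measure the spread between these cultures, since the labels do not say that each came from a separate donor.

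For 23 gene lists limma's camera was run with a preset inter-gene correlation of 0.01 (2-sided, adjusted over the lists), and beside it camera with a correlation estimated from the data and fry, a rotation test of whether a list's genes move one way on balance. For each list the members past the threshold were also counted with p adjusted over the list alone. The lists covered Hedgehog, TGF-beta and BMP, and Wnt signalling, growth factors, contractile genes, inflammatory cytokines, collagens, matrix glycoproteins, matrix proteases, proliferation, p53 targets, interferon response, HOX genes, fibroblast identity, hypoxia and glycolysis, and sterol synthesis. Markers of other cells that a culture could hold made up the remaining lists, namely epithelial, acinar and endocrine, endothelial, immune, pericyte, neural and mesothelial markers. For single Hedgehog genes an exact permutation test (2-sided, on the absolute difference of means) was run over all 220 splits of the arrays, where the smallest possible p is 0.00455. These tests and the correlations between arrays were run in R. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 was used to prepare the values and to correlate list means among the CAF.

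The design, the gene lists, the processing alternatives and the rule for named genes were fixed before the data were examined. The rule names up to 10 genes per direction with the largest difference past the threshold, filled to 10 by the smallest p among genes with a difference of at least 1 and then reported as values only. It also names a set of Hedgehog genes, of which SMO, GLI1, GLI2, GLI3 and HHIP were analysed here and 1 was not analysed here, up to 4 members of each list with the smallest p, and the 5 genes with the smallest p for exon usage. Where another gene is named, it was chosen after its values were seen.

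Alternatives changed the gene summary, the scaling between arrays, the filter on dim genes, the minimum of probesets, the variance model, the kind of list test and the arrays entering the fit, each array being left out in turn. The proliferation list mean as a covariate, and leaving out control 1 and CAF 8 together, were added after the data were seen. The steps were tested on simulated data made from the spread of these arrays. Of 50 genes changed by 1, 2, 3 or 4 log2 units each among 11489, the gene test recovered 46%, 72%, 96% and 100%, with 4 false calls. Among 178161 probesets the share was 0%, 32%, 72% and 82%, with 6 false calls. All 4 shifted lists of 23 were recovered with 0 false calls. Simulated genes varied independently of each other, while the correlation estimated from the data reached 0.731 in the proliferation list. The simulation therefore cannot tell how often camera calls correlated lists falsely in these data. Simulated probesets were independent too, and the simulated arrays shared no structure beyond the groups. The false calls of the gene, probeset and exon usage tests hold for such data only. For exon usage, 160 of 200 changed genes among 13467 were recovered beside 55 false calls, so 25.6% of the simulated calls were false, above the nominal 5%.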

Results

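Gene expression was measured in 12 fibroblast cultures from human pancreas. The 9 CAF cultures came from ductal adenocarcinoma. The 3 controls were HPNE, an established line that the labels describe as immortalized fibroblasts of normal pancreas (control 1), a culture labelled as from an IPMN tumor (control 2) and a culture from chronic pancreatitis (control 3). The series gives 3 controls and 9 CAF without saying which is which. Control 2 was counted as a control by inference, since the label ductal adenocarcinoma is carried by 9 other cultures, and each CAF against control value rests on that grouping. Each culture was hybridised to 1 array, and all values are log2 RMA signals. The study asked how gene expression differs between CAF and control fibroblasts.

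The CAF cultures resembled each other more than the controls did. Over the 11489 genes tested, Pearson's r between arrays averaged 0.92 (SD 0.035, 36 pairs) within CAF, 0.876 (SD 0.0389, 27 pairs) between CAF and control, and 0.848 (SD 0.00948, 3 pairs) within the controls. These correlations run across genes, which are not independent replicates. The nearest culture of each control was a CAF: CAF 7 for control 1 (r = 0.901), CAF 6 for control 2 (r = 0.929) and CAF 9 for control 3 (r = 0.945). The first principal component held 26.6% of the variance and did not part the groups, with control 1, control 2 and CAF 6 at its low end (-49.7, -43.4 and -40.2) and CAF 2 at its high end (35.3).

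TERT was higher in the controls than in the CAF cultures, and 7 genes were higher in CAF. TERT, the catalytic subunit of telomerase, was lower in CAF, at 4.74 ± 0.30 (SD, n = 9) against 9.36 ± 0.58 (SD, n = 3), a difference of -4.62 ± 0.25 (SE) with adjusted p = 5.78e-07. Some of its probesets lay at or under the floor of the arrays in CAF (lowest mean 2.26), so no fold is given. All 3 controls held high TERT (8.91 to 10.01) and every CAF lay between 4.35 and 5.34, although the labels call only control 1 immortalized. Each difference between the groups given here is therefore also one between cultures of high and of low TERT. The keratin gene KRT7, an intermediate filament of simple epithelia, was higher in CAF by 4.31 ± 0.56 (SE, adjusted p = 0.00792), at 9.19 ± 0.93 against 4.88 ± 1.06 (SD). Its probeset 3415351 averaged 2.73 in the controls, at the floor, so no fold is given. NDN, which encodes the growth suppressor necdin, was higher by 2.58 ± 0.23 (SE, adjusted p = 2.08e-04). Its controls lay near the floor (2.57 to 3.69), so a fold is not given either, and of its 4 probesets 2 differed by 6.10 and 4.19 and 2 by 0.023 and -0.0022. GDF15, a stress-induced cytokine and p53 target, rose 5.31-fold (2.41 ± 0.29, SE, adjusted p = 0.00383). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose 2.34-fold (1.22 ± 0.19, SE, adjusted p = 0.0346).

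The early response gene IER3 was 3.83-fold higher in CAF (1.94 ± 0.29, SE, adjusted p = 0.0258), and SPATC1L 3.33-fold (1.73 ± 0.27, SE, adjusted p = 0.0346). KLHL13, an adaptor of a ubiquitin ligase, was higher by 2.15 ± 0.35 (SE, adjusted p = 0.0469), with all controls near the floor (2.47 to 2.85), so again no fold is given. For each of the 8 genes all 9 CAF lay on one side of all 3 controls. Such separation was seen in 160 genes with CAF above and 62 with CAF below, 1.93% of the genes tested, where chance gives 0.909%. At an unadjusted p under 0.05 there were 1115 genes, 720 higher and 395 lower in CAF, and the median difference of all genes was 0.087. Of all 11489 genes tested 7084 lay higher in CAF, and counts of list members that lay higher are to be read against this share. TERT, NDN and GDF15 kept their calls when any 1 of the 12 arrays was left out. Without control 1 the calls were lost for KRT7 (difference 3.90, adjusted p = 0.0902), IER3 (2.09, 0.0902), CDKN1A (1.20, 0.194), SPATC1L (1.42, 0.228) and KLHL13 (2.09, 0.239), while all 5 differences kept their direction. Without control 2 the adjusted p was 0.0714 for CDKN1A (1.10) and for KLHL13 (2.08). Leaving out 1 CAF culture gave up to 0.0678 for IER3 (CAF 2, 3, 4 or 5), 0.0789 for SPATC1L (CAF 2, 3, 4, 5 or 7), 0.0822 for CDKN1A (CAF 1, 2, 3, 4, 5 or 7) and 0.106 for KLHL13 (CAF 1, 2, 3, 5, 7 or 9). Without variance moderation the adjusted p was 0.112 for KRT7, 0.123 for IER3, 0.142 for SPATC1L, 0.0752 for CDKN1A and 0.213 for KLHL13, and with array weights it was 0.0810 for SPATC1L, 0.0503 for CDKN1A and 0.108 for KLHL13. The count of genes was 3 without control 1, 25 without control 2 and 85 without control 3.

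**Figure D1:**
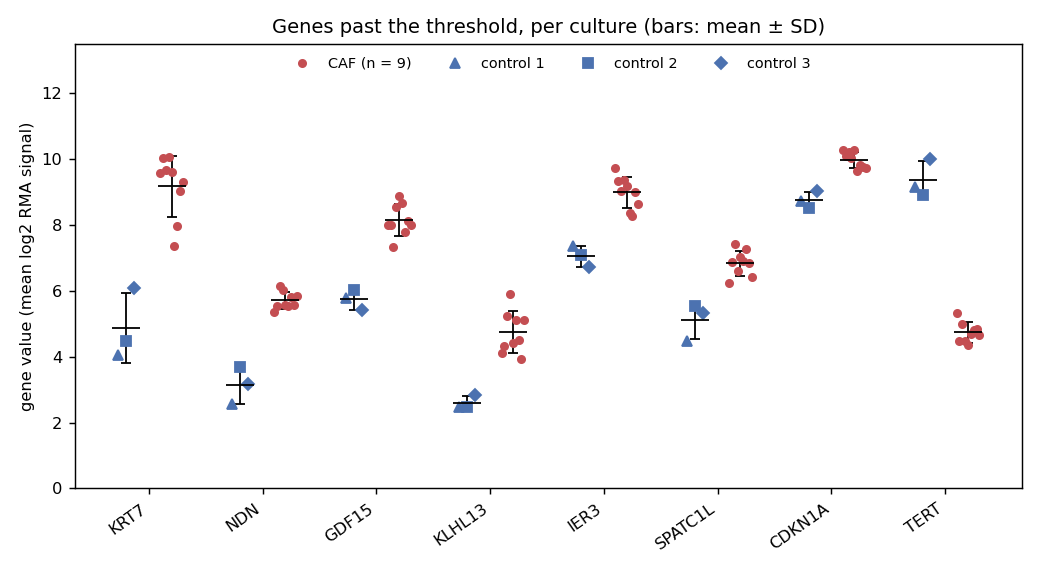
Gene values (mean log2 RMA signal, vertical axis) of the 8 genes past the threshold, 1 point per culture, with CAF (n = 9) as circles and each control by its own symbol, and bars for mean ± SD. TERT lies between 8.91 and 10.01 in the controls and between 4.35 and 5.34 in CAF, and in the other 7 genes every CAF lies above every control.

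No other gene passed the threshold over all genes, and the following are values only. ST6GALNAC5, a sialyltransferase, differed by 3.39 ± 0.62 (SE, adjusted p = 0.109). PMEPA1, a TGF-beta target that restrains the pathway, differed by 2.21 ± 0.42 (adjusted p = 0.131) and the microtubule-binding MAPRE3 by 1.53 ± 0.29 (adjusted p = 0.133). On the lower side the adhesion molecule ALCAM differed by -1.21 ± 0.24 (adjusted p = 0.136), HERC3 by -1.44 ± 0.26 (0.109) and the sodium channel SCN2A by -1.59 ± 0.31 (0.136). NCKAP5 differed by -1.88 ± 0.38 (0.141), the urea cycle enzyme CPS1 by -1.47 ± 0.30 (0.141), the synaptic adhesion gene NLGN1 by -1.83 ± 0.38 (0.141) and MYPN by -1.78 ± 0.39 (0.189). ST6GALNAC5 was 4.96 in CAF 9 against 7.0 to 9.06 in the other CAF, ALCAM was 7.88 in CAF 8 against 8.46 to 9.03, and SCN2A was 3.67 in CAF 7 against 2.23 to 2.93. NCKAP5 was 7.04 in control 2 against 4.69 and 5.16 in the other controls and differed by -1.18 without it. MYPN was 6.24 in control 1 against 4.11 and 4.06 and differed by -1.06 without it. With 1 array left out some of these genes passed the threshold. Without control 3 these were PMEPA1 (adjusted p = 0.0459), HERC3 (0.0361), SCN2A (0.0346) and MYPN (0.0452), and without CAF 6 PMEPA1 (0.0166), HERC3 (0.0231) and MAPRE3 (0.0417). MAPRE3 passed without control 2 (0.0302) and with medians of probesets (0.0201), ALCAM without CAF 8 (0.0352) and ST6GALNAC5 without CAF 9 (0.00324).

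Genes of cell division were lower in CAF as a group and targets of p53 were higher. All 32 tested members of the proliferation list lay lower in CAF, with a mean difference of -1.0. The list fell by camera (adjusted p = 2.85e-14, and adjusted p = 0.398 with an estimated correlation). No member passed over all genes and 2 passed when adjusted over the list alone, the spindle checkpoint kinase TTK (-1.51 ± 0.40, SE) and the kinetochore gene CENPF (-2.15 ± 0.58). The mitotic motor KIF11 (-1.69 ± 0.52) and the topoisomerase TOP2A (-2.20 ± 0.74) did not. List means ran from 4.48 to 6.56 in CAF and from 5.48 to 7.41 in controls, so 5 of 9 CAF lay within the range of the controls. In the list of p53 targets and cell cycle inhibitors 22 of 23 members lay higher, by 0.64 on average. The list rose by camera (adjusted p = 6.91e-08, and adjusted p = 0.288 with an estimated correlation). GDF15 and CDKN1A passed over all genes, and these and the death receptor TNFRSF10B (0.95 ± 0.22, SE) passed when adjusted over the list alone, while BTG2 (0.69 ± 0.23, and 0.43 without control 1) did not. Each CAF list mean (6.55 to 7.47) lay above each control's (6.27 to 6.49), as was also so for the inflammatory and the neural and glial lists. The p53 list was the only one with a call by fry (adjusted p = 0.0478, with 0.0509 for the inflammatory list). The proliferation and p53 lists both kept the camera call without each of the 3 controls. The mean difference of the proliferation list was -0.52 without control 1 and -1.50 without control 2.

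Interferon-stimulated genes lay lower in CAF, 17 of 21 tested members, with a mean difference of -0.72. The list fell by camera (adjusted p = 7.74e-07, and adjusted p = 0.398 with an estimated correlation). The antiviral genes IFIT3 (-2.51 ± 0.52, SE), IFIT1 (-1.84 ± 0.41) and IFIT2 (-1.40 ± 0.40) passed when adjusted over the list alone and none passed over all genes. The RNA sensor RIGI (-1.0 ± 0.39, and -0.24 without control 2) passed neither. Control 2 alone had a list mean of 8.01, against 5.65 and 5.16 in the other controls and 5.08 to 5.93 in CAF. Without control 2 the mean difference turned to 0.13 with adjusted p = 0.595, and without control 3 it was -1.28.

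Matrix and contractile genes were higher on average in CAF as groups. Of the 9 CAF list means, 8 lay within the range of the controls for contractile genes, and 2 each for collagens and for glycoproteins. Of the collagens and collagen processing genes 27 of 31 lay higher, by 0.65 on average (camera adjusted p = 1.06e-05, and adjusted p = 0.398 with an estimated correlation). None passed over all genes and 8 passed when adjusted over the list alone. Among them were the basement membrane collagens COL4A1 (1.30 ± 0.40, SE) and COL4A2 (0.99 ± 0.33), COL6A2 (0.73 ± 0.23) and the collagen chaperone SERPINH1 (0.73 ± 0.23). With 1 array left out the difference ran from 0.94 to 1.91 for COL4A1 and from 0.71 to 1.55 for COL4A2. All 16 contractile genes of myofibroblasts lay higher, by 0.86 on average (camera adjusted p = 1.06e-04, and adjusted p = 0.398 with an estimated correlation), with 0 past the threshold by limma over all genes or adjusted over the list alone and 5 at an unadjusted p under 0.05. Calponin (CNN1) differed by 2.39 ± 0.70, smooth muscle actin (ACTA2) by 2.15 ± 0.67, TAGLN by 1.00 ± 0.36 and tropomyosin TPM2 by 0.82 ± 0.32. ACTA2 was 7.73 in control 1, 12.70 in control 2 and 9.80 in control 3, against 11.83 to 12.49 in CAF, so no CAF lay above all controls. TAGLN was 10.46 in CAF 9 against 10.93 to 11.39 in the other CAF. Of the matrix glycoproteins and proteoglycans 26 of 33 lay higher, by 0.86 (camera adjusted p = 0.00794, and adjusted p = 0.547 with an estimated correlation). Past the threshold by limma were 0 on either adjustment, and 6 had an unadjusted p under 0.05, with the microfibril gene MFAP5 at 3.21 ± 1.40 and the collagen-binding FMOD at 2.13 ± 0.79. MFAP5 was 3.19, 6.77 and 11.38 in controls 1, 2 and 3, and its difference was 1.24 without control 1 and 5.34 without control 3. Without control 1 the adjusted p was 0.156 for the collagens (mean difference 0.40), 0.240 for the contractile genes (0.39) and 0.683 for the glycoproteins (0.32), whose direction against all other genes then turned. Without control 2 the mean difference of the contractile genes was 1.56, and ACTA2 (3.46, adjusted p = 0.00354), TAGLN (1.68, 0.0153) and CNN1 (3.55, 0.0302) then passed over all genes. Without control 1 these differences were 0.98, 0.57 and 1.28 (adjusted p = 0.629, 0.712 and 0.607), and that of TPM2 was 0.35.

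The lists of inflammatory genes, of TGF-beta and BMP signalling and of hypoxia and glycolysis were also called higher in CAF. Of the inflammatory cytokines and chemokines 13 of 15 lay higher, by 0.98 on average (camera adjusted p = 2.93e-04, and adjusted p = 0.288 with an estimated correlation). None passed over all genes and 3 passed when adjusted over the list alone, the hyaluronan-binding TNFAIP6 (2.23 ± 0.56, SE), the cytokine IL6 (2.33 ± 0.67) and the prostaglandin synthase PTGS2 (2.31 ± 0.70), with the cytokine LIF at 1.80 ± 0.70. The TGF-beta and BMP list had 21 of 28 members higher, by 0.52 (camera adjusted p = 0.0105, and adjusted p = 0.459 with an estimated correlation), with 0 over all genes and PMEPA1 alone past the threshold adjusted over the list alone. The hypoxia and glycolysis list had 22 of 24 higher, by 0.40 (camera adjusted p = 0.0110, and adjusted p = 0.398 with an estimated correlation). By limma 0 passed on either adjustment and 3 lay at an unadjusted p under 0.05. These were ANKRD37 at 1.96 ± 0.76 and NDRG1 at 0.81 ± 0.34 (0.21 without control 1), both induced by hypoxia, and the glucose transporter SLC2A3 at 0.44 ± 0.19. The glycolytic enzyme ALDOA, at 0.33 ± 0.16, did not reach that mark. Without control 1 the adjusted p was 0.0748 for the inflammatory list (mean difference 0.72) and 0.971 for the TGF-beta list (0.15), and without control 3 it was 0.134 for the hypoxia list (0.32).

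**Figure D2:**
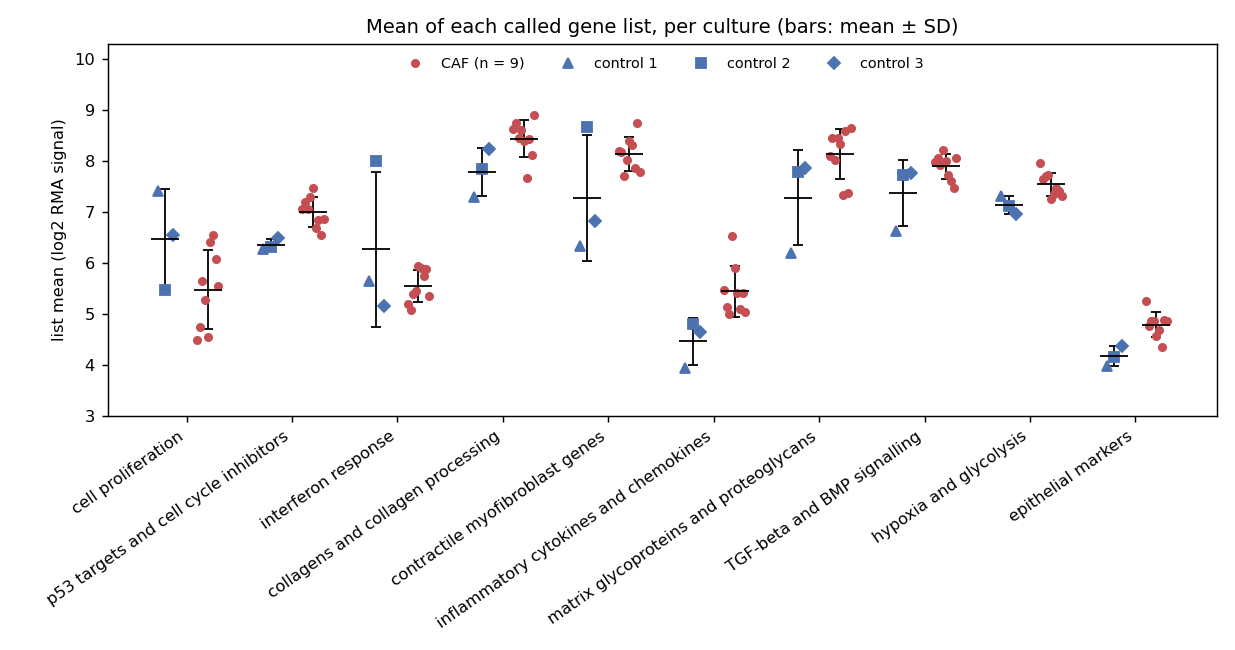
Mean log2 RMA signal (vertical axis) of each of the 10 gene lists called by camera, 1 point per culture, with CAF (n = 9) as circles and each control by its own symbol, and bars for mean ± SD. In the p53 list all CAF (6.55 to 7.47) lie above all controls (6.27 to 6.49), and in the interferon list control 2 stands at 8.01 with all other cultures between 5.08 and 5.93.

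Among markers of other cell types the epithelial list was called higher in CAF (10 of 10 tested members, mean 0.61, median 0.17, camera adjusted p = 0.0322, and adjusted p = 0.547 with an estimated correlation), and KRT7 was its only member past the threshold, over all genes and adjusted over the list alone. The adhesion molecules of epithelia were near the floor in both groups, EPCAM at 2.96 ± 0.23 (SD, n = 9) against 2.90 ± 0.17 (n = 3) and CDH1 at 3.40 ± 0.32 against 3.03 ± 0.27. Several keratins were well above the floor. KRT8 was 9.53 in CAF and 9.36 in controls, KRT18 was 9.03 and 8.22 and KRT19 was 7.28 and 5.19. KRT19 and KRT18, with too few probesets for the test, were 2.09 and 0.80 higher in CAF, and MUC1 differed by 0.64 ± 0.37 (SE), and by 0.20 without control 1. The epithelial call was lost without control 1 (adjusted p = 0.240), control 2 (0.0615), CAF 1 (0.0927), CAF 6 (0.0602), CAF 8 (0.0633) or CAF 9 (0.0792). With no filter on dim genes it was lost too (21 members, mean 0.30, adjusted p = 0.170), and at the stricter filter the mean was 1.71 over 3 members. Mesothelial markers were not called (6 of 8 higher, camera adjusted p = 0.192), with the transcription factor WT1 (1.00 ± 0.25, SE) past the threshold adjusted over the list alone and none over all genes. Neural and glial markers (8 of 9 higher, adjusted p = 0.0707), endothelial (6 of 7 higher, 0.473), immune (5 of 7 higher, 0.577) and acinar and endocrine markers (5 of 7 higher, 0.577) were not called. The neural list was called on quantile normalizing again (0.0372) and without CAF 2, 5 or 7 (0.0393 to 0.0403), and the mesothelial list with genes of 1 or more probesets (0.0111). The neural, endothelial, immune and acinar lists had 0 members past the threshold by limma on either adjustment and at most 1 at an unadjusted p under 0.05.

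The remaining lists were not called by camera and had 0 members past the threshold on either adjustment. Sterol synthesis genes had 13 of 17 members lower (mean -0.18, adjusted p = 0.0655), and matrix proteases and inhibitors had 17 of 24 higher (mean 0.51, adjusted p = 0.0707), with TIMP3, an inhibitor of metalloproteinases, at 2.57 ± 0.95 (SE; 0.88 without control 1). The sterol list was called in 6 alternatives, among them without control 2 (mean -0.49, adjusted p = 2.14e-04) and control 3 (-0.35, 0.0103), and turned to 0.29 without control 1. The protease list was called in 4, without control 2 (0.78, 0.00173), control 3 (0.59, 0.0231) or CAF 8 (0.57, 0.0426) and with medians of probesets (0.61, 0.0316), and its camera direction turned without control 1 (0.17). HOX genes (20 of 27 higher, adjusted p = 0.235), Wnt signalling (14 of 24 higher, 0.652) and fibroblast and stellate cell identity (19 of 28 higher, 0.577) were likewise not called. Among them the secreted ligand WNT5A differed by -1.85 ± 0.70 and the intermediate filament gene NES by -1.58 ± 0.50, which was -0.89 without control 2 and passed over all genes without control 3 (-2.55, adjusted p = 0.00221). Growth factors and receptors split evenly, 15 higher and 15 lower, with mean 0.19 and median 0.0021 but a camera direction that was lower (adjusted p = 0.785), the receptor MET at -0.96 ± 0.32 and the ligand KITLG at -1.74 ± 0.56. Pericyte and smooth muscle markers had mean 0.075 and median 0.23, again with a lower camera direction (adjusted p = 0.870). At an unadjusted p under 0.05 these lists held between 0 and 6 genes in a direction.

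The study examined Hedgehog signalling, the pathway in which SMO carries the signal across the membrane to the GLI transcription factors. SMO was higher in CAF, at 6.08 ± 0.45 (SD, n = 9) against 4.86 ± 0.72 (SD, n = 3), and 7 of 9 CAF lay above all controls. Its probeset 3023369 averaged 2.88 in the controls, at the floor, so no fold is given. The SMO difference of 1.22 ± 0.32 (SE) did not pass over all genes (adjusted p = 0.247) and passed when adjusted over the list alone (adjusted p = 0.0320, 1 of 16 members). It gave an exact permutation p of 0.0136 (0.0682 adjusted over 5 genes). SMO was singled out by the study on these samples, so the list count is not independent evidence. The transcription factors GLI1 (0.17 ± 0.17, SE, exact p = 0.264), GLI2 (0.42 ± 0.22, exact p = 0.1) and GLI3 (-0.15 ± 0.36, exact p = 0.705) had differences that did not pass. Without 1 array they ran from 0.095 to 0.28 for GLI1, 0.065 (without control 1) to 0.64 for GLI2 and -0.32 to -0.061 for GLI3. The difference did not pass either for the pathway inhibitor HHIP (-0.85 ± 0.83, exact p = 0.405), which was 2.99 in control 2 and 7.77 and 8.19 in the other controls. The Hedgehog list as a whole was not called (11 of 16 higher, mean 0.10, camera adjusted p = 0.539). SMO lost its place past the threshold over the list without control 1 (difference 0.99, adjusted p = 0.149) or control 2 (1.03, 0.109), and without CAF 1, 2, 3, 4 or 7 (1.19 to 1.23, up to 0.0636). The same held with medians of probesets (1.17, 0.129), arrays quantile normalized again (1.15, 0.0777) or no variance moderation (0.0826). Without control 3 SMO passed over all genes (1.64, adjusted p = 0.0377) and HHIP turned to 0.085. Without control 2 HHIP was -2.51, missing the threshold over all genes (adjusted p = 0.0513) and passing when adjusted over the list alone (0.00225), with both remaining controls above every CAF (4.28 to 6.44).

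**Figure D3:**
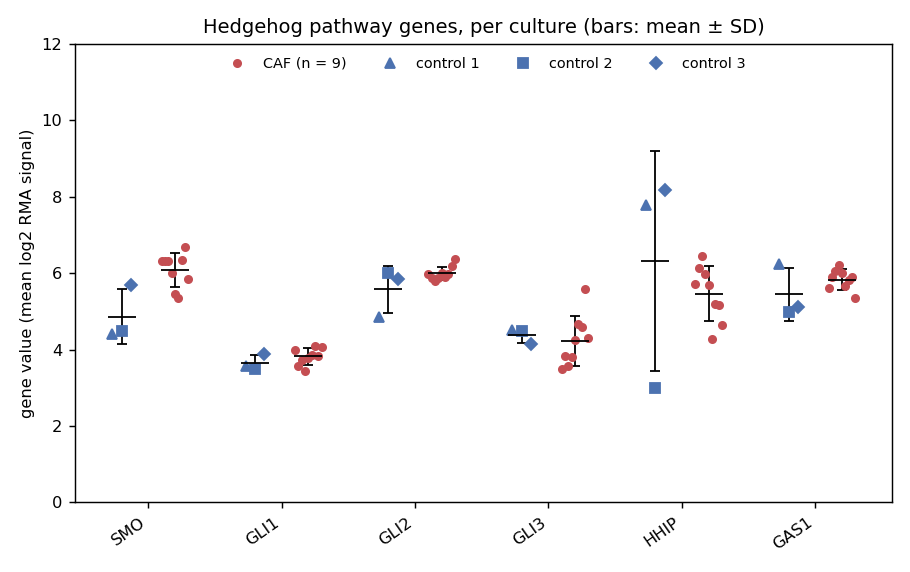
Gene values (mean log2 RMA signal, vertical axis) of 6 Hedgehog pathway genes, 1 point per culture, with CAF (n = 9) as circles and each control by its own symbol, and bars for mean ± SD. SMO averages 6.08 in CAF and 4.86 in controls with 7 of 9 CAF above all controls, and HHIP ranges from 2.99 to 8.19 among the controls.

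Among single exon probesets TERT and KRT7 held the most calls. Of 178161 probesets 48 passed the threshold, 22 higher and 26 lower in CAF, in 11 genes. TERT held 23 of them, KRT7 7, GDF15 5, KLHL13 4, NDN 2 and the neural adhesion gene CNTN5 2, and DEAF1, IER3, MYPN, SIRPA and ST6GALNAC5 held 1 each. For TERT 28 of 29 probesets lay over 1 log2 unit lower in CAF and for KRT7 10 of 10 lay over 1 higher. The count was 239 without control 2, 631 without control 3 and 94 without CAF 6.

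The exon usage test (limma's diffSplice F test) called 16 of 13467 genes, with 355 at an unadjusted p under 0.05. A call means that probesets of a gene differed by unequal amounts and does not by itself show alternative exons. The leading genes were TERT (adjusted p = 2.05e-74), SEZ6L2 (5.00e-08), NDN (5.00e-08), INPP5F, a phosphoinositide phosphatase (9.15e-08), and NBEA, a vesicle trafficking gene (1.87e-04). Probeset differences in TERT ran from -8.16 to 0.54, the last at probeset 2845830, in SEZ6L2 from 0.018 to 3.63 and in NDN from 0.023 to 6.10 over the 3 probesets tested. In INPP5F they ran from -1.43 to 2.65 around a gene difference of 0.032 ± 0.20 (SE, adjusted p = 0.968), and in NBEA from -2.45 to 0.26. KRT7 and SMO were also among the 16. The call for INPP5F was lost without control 1 (adjusted p = 0.668) and at the stricter filter on dim probesets (0.0975), that for NBEA without control 2 (0.303) and by the Simes test (0.242), and the count was 8 without control 1 and 127 without control 3.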

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

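The tests of TERT overlap, of the KRT7 markers and probesets, of the exon usage calls and of the interferon list without single controls, and the use of the proliferation mean as a covariate, were chosen after the result was seen. In 96 sets of values over the 9 CAF, the most extreme culture stood apart in 6 by a gap of more than 0.493 of the range, and chance gives about 1 in 20. ST6GALNAC5 was 4.96 in CAF 9 (others 7.0 to 9.06), ALCAM was 7.88 in CAF 8 (others 8.46 to 9.03) and SCN2A was 3.67 in CAF 7 (others 2.23 to 2.93). TAGLN was 10.46 in CAF 9 (others 10.93 to 11.39) and TGFB3, a TGF-beta ligand, was 5.83 in CAF 9 (others 3.65 to 4.74). The mean of the fibroblast and stellate identity list was 6.23 in CAF 8 (others 6.67 to 7.06), the culture with the widest relative log expression.

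The p53 list rose and the proliferation list fell in CAF, while TERT was high in every control. Both lists kept the camera call, at the preset correlation, without any 1 control. The highest camera adjusted p was 2.84e-05 for the p53 list and 9.40e-05 for the proliferation list, each without control 1. Whether the calls depend on 1 control cannot be decided by this test for either list. The estimated correlations, 0.186 for the p53 list and 0.731 for the proliferation list, lay above the preset one. The size of the p53 difference changed little with 1 array left out, at 0.59 to 0.71. The proliferation difference went from -1.0 to -0.52 without control 1. List means were 7.41 in control 1, 5.48 and 6.55 in controls 2 and 3, and 4.48 to 6.56 in CAF. Slower growth of the CAF cultures may account for part of the p53 difference: with the proliferation mean as a covariate it was 0.43 (95% interval 0.058 to 0.79) against 0.64 without, an interval from below 0.32, the mark set for the test, to above 0.64, so the part was not settled. A telomerase effect cannot be told apart from a difference between CAF and control, since 0 CAF reached the TERT level of any control. This holds for every gene and list compared between the groups, not only for these lists. The tumour origin of the CAF, which the design names, stays open and untested.

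KRT7 was higher in CAF by 4.31 log2 units. Epithelial cells that raise the markers as a set, by a median over 1 log2 unit, are argued against. The other 23 epithelial markers had a median difference of 0.13 (95% bootstrap interval 0.0074 to 0.19), with EPCAM at 2.96 in CAF and 2.90 in controls. A smaller share of epithelial cells stays open, since many of these markers lay near the floor in both groups. KRT19 and KRT18 stood at 2.09 and 0.80, with too few probesets for the test over the list. Mesothelial cells stay open: the median was 0.35 (95% bootstrap interval -0.016 to 0.80) over 13 markers that went both ways, WT1 passed over its list at 1.00, KRT19, which like KRT8 and KRT18 is in both lists, stood at 2.09, and the list was called with genes of 1 or more probesets (adjusted p = 0.0111). A single faulty probeset is argued against, since 10 of 10 KRT7 probesets lay over 1 log2 unit higher. A keratin gene expressed by the CAF themselves is a hypothesis that these values leave open, and without control 1 the difference was 3.90 with the call lost (adjusted p = 0.0902).

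Of the 16 genes called for exon usage 13 were also tested as genes, and 12 of these (92.3%) had a gene-level p under 0.05, against 9.65% of the other 11311 (Fisher's exact test p = 8.27e-12). Whole-gene change read by probesets of unequal response and alternative exons cannot be told apart by this, since a gene's value averages the same probesets. In NDN 2 of 4 and in SMO 8 of 18 probesets were over 1 log2 unit higher. The other NDN probesets lay near the floor in both groups, at 2.09 and 3.42 in CAF and 2.09 and 3.40 in controls. The NDN call may therefore come from probesets that do not respond. In the simulation 25.6% of exon usage calls were false. INPP5F was the 1 of the 13 without a gene-level difference, and its call was lost without control 1 (adjusted p = 0.668) and at the stricter filter (0.0975).

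For the interferon list, leaving out 1 control gave a camera adjusted p of up to 0.595, without control 2. Chance was not excluded for any of the 4 counts, by 100 of the 220 splits of the 12 arrays into 9 and 3, the real one included. At least as many genes as the real 8 came from 6 splits (highest other 310), as many probesets as the real 48 from 7 (highest other 2873), as many lists as the real 10 from 14 (highest other 16) and as many exon usage genes as the real 16 from 25 (highest other 641). The split with 310 genes and 2873 probesets set control 1, control 2 and CAF 6 against the rest, the 3 cultures at the low end of the first principal component. This split keeps control 1 and control 2 and puts CAF 6 in the place of control 3, so it is not independent of the real grouping. Whether its higher counts come from a structure of the samples other than CAF against control was not tested. The split with 641 exon usage genes set control 3, CAF 8 and CAF 9 apart, and that with 16 lists control 1, CAF 2 and CAF 5.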

How the results depend on the processing

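The proliferation covariate and the removal of control 1 and CAF 8 together were chosen after the data were seen, and the cause of changes was not tested unless it follows from fewer arrays. No paired analysis was possible because the labels carry no replicate numbers that the groups share. The 8 genes became 4 with array weights, 3 without variance moderation, 4 with the covariate and 2 without control 1 and CAF 8, with 3 (without control 1) to 85 (without control 3) when 1 array was left out, and quantile normalizing again gave 6 higher and 2 lower where 7 and 1 stood before. TERT passed in all 24 alternatives (-5.15 to -4.29), NDN in all 23 that tested it, and GDF15 in 22 of 24 (adjusted p = 0.0503 with array weights and 0.0860 without control 1 and CAF 8). Of 24 alternatives KRT7 passed in 21, IER3 in 16, SPATC1L in 13, CDKN1A in 11 and KLHL13 in 8. Outside single arrays left out, KLHL13 was also lost on quantile normalizing (0.0597), centring (0.0616), without a filter (0.0941) and with 1 or more probesets (0.0517), SPATC1L without a filter (0.0544) and CDKN1A with medians (0.152). With the covariate these 3 and IER3 were lost (0.141 to 0.214), and without control 1 and CAF 8 all 5 (0.146 to 0.223). Further genes that passed over all genes with an array left out were TTK (0.0302), CENPF (0.0375) and COL4A2 (0.0395) without control 2, IFIT3 (0.0346), TNFRSF10B (0.0489), WT1 (0.0249), the activin antagonist FST (0.0183) and the Wnt receptor ROR2 (0.0492) without control 3, and SEZ6L2 without CAF 8 (0.0340). With the covariate the 10 lists became 6 of 22, since the proliferation list was the covariate and was not tested. Camera calls lost there were glycoproteins (mean 0.47, adjusted p = 0.407), TGF-beta (0.21, 0.475) and epithelial markers (0.48, 0.109). The 10 lists became 5 without control 1 and CAF 8, 0 with an estimated correlation (2 at an unadjusted p under 0.05), 1 by fry (7 at an unadjusted p under 0.05), and 4 (without control 1) to 12 with 1 array left out. The 48 probesets became 30 without moderation and 33 to 631 with 1 array left out, and the 16 exon usage genes 76 without a filter, 10 at the stricter filter and 8 to 127 with 1 array left out. The Hedgehog count of 1 became 0, with SMO at 1.17 (medians of probesets), 1.15 (quantile), 1.22 (no moderation), 1.25 (covariate) and 0.91 (without control 1 and CAF 8), and was 0 to 1 with SMO at 0.99 to 1.64 with 1 array left out. The mean r within controls, between groups and within CAF was 0.766, 0.804 and 0.868 from bright probesets only, and the first 2 were 0.907 and 0.925 without a filter and 0.781 and 0.823 at the stricter filter. Among genes direction turned in 3: INPP5F was -0.55 with medians, -0.021 with quantile, -0.0056 with the covariate and -0.054 to 0.12 with 1 array left out, GLI3 was 0.23 with the covariate and HHIP -2.51 to 0.085 with 1 array left out. For lists the camera direction turned, at the following mean differences. With medians growth factors were at 0.22, with quantile pericyte markers at 0.010, without a filter acinar at 0.042 and pericyte at 0.091, at the stricter filter Wnt at 0.24, with the covariate sterol at 0.016 and pericyte at 0.073, and by fry growth factors at 0.19 and pericyte at 0.075. Without control 1 and CAF 8 they were Hedgehog 0.041, glycoproteins 0.42, Wnt 0.087, fibroblast identity 0.15, sterol 0.31 and acinar 0.071. With 1 array left out the mean differences ran from 0.062 to 0.16 (Hedgehog), 0.32 to 1.15 (glycoproteins), 0.17 to 0.78 (proteases), 0.073 to 0.33 (Wnt), -0.036 to 0.46 (growth factors), 0.073 to 0.50 (fibroblast identity), -0.49 to 0.29 (sterol), -0.058 to 0.25 (pericyte) and -1.28 to 0.13 (interferon). Genes near the floor of about 3 log2 units limit what a difference there can show.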

Other observations

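The correlation within CAF was chosen after the result was seen, and the other values here were not tested. Control 1, the HPNE line, held low levels of several transcripts abundant in all other cultures. THY1, a surface marker of fibroblasts, was 5.02 in control 1 and 10.66 to 11.65 in the other 11 cultures, and the mesenchymal cadherin CDH11 was 3.45 against 9.56 to 10.94. The growth factor binding protein IGFBP5 was 3.23 against 9.46 to 11.73, TIMP3 was 4.20 against 7.80 to 11.02 and the TGF-beta pseudoreceptor BAMBI was 3.25 against 7.94 to 9.63. The difference between the groups was 2.14 ± 0.92 (SE) for THY1 and 3.26 ± 1.09 for IGFBP5, and without control 1 it was 0.12 and 0.96.

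The CAF cultures differed widely among themselves in some genes. The neurofilament gene NEFM was 8.31 in CAF 1, 8.29 in CAF 8 and 7.47 in CAF 5, and 2.73 to 5.10 in the other CAF, against 2.61 to 2.87 in controls. The hyaluronan link protein gene HAPLN1 lay between 6.27 and 7.60 in CAF 1, 2, 3 and 4 and at 5.87 in CAF 9, against 2.49 to 3.79 in the other CAF and 2.47 to 3.15 in controls. MFAP5 was 7.04 in CAF 6 and 7.58 in CAF 8 and 10.21 to 11.70 in the other CAF. PTGS2 ranged from 3.45 in CAF 8 to 8.34 in CAF 4, and control values were 3.44 to 3.95.

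Among the 9 CAF the p53 list mean was lower where the proliferation list mean was higher, with Pearson's r = -0.775 (exact permutation p = 0.0164) and Spearman's rho = -0.762 (exact permutation p = 0.0213). Adjusted over the 22 lists set against proliferation these were 0.361 and 0.468, so the relation did not pass. Without CAF 1 and CAF 7, the cultures farthest from the median proliferation, r was -0.888.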
